A study of Mus musculus with 8 samples.

How the data were processed

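Dermal fibroblasts isolated from the skin of newborn C57BL/6 mice were transfected in culture either with control oligonucleotides (4 samples) or with a mimic of the microRNA miR-127-3p (4 samples), per the labels. A mimic is a short synthetic RNA duplex that stands in for the mature microRNA. Per the series' design text, RNA was taken up in phenol-chloroform, amplified and labelled with a low-input kit, hybridised to a mouse gene expression array of long oligonucleotide probes, and analysed by the authors in GeneSpring 14.9.1 and FunRich. Each sample was read in a single dye (Cy3) on its own array. All 8 arrays lay on 1 slide and came from 1 scan, with samples 1 to 4 in the slide's row 1 and samples 5 to 8 in row 2.

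The scanner tables hold intensity values per spot that the authors obtained with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity is background-subtracted and detrended within the array but not normalized between arrays, per the file headers. The deposited value table of the series holds log2 values per probe. Set against the scanner signals, each of its columns equals the log2 processed intensity minus 1 constant per array (the offset had an SD of at most 2.78e-07 over probes). Its columns have 75th percentiles between -0.000485 and -0.0000806 and medians of -3.78, -3.68, -3.60, -3.69, -3.68, -3.62, -3.60 and -3.67 for samples 1 to 8, so its scale is log2, its reference is each array's 75th percentile, and genes were not centred. How GeneSpring was used on it beyond this is not given in the sources used here.

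Each array held 62976 spots, of which 3671 were controls. Control spots and spots flagged as outliers were left out, and spots of the same probe were averaged on the log2 scale, which gave 55681 probes. Each array's 75th percentile over these probes was subtracted from its log2 processed signal. Probe accessions, taken without versions, were matched to gene symbols in a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names alone. They matched for 28331 probes (21368 symbols), and 27350 probes kept the name given in the file. A probe was tested if it was well above background on at least 4 of the 8 arrays, which 21971 probes were, and 7 of these dropped out because their only spot was an outlier on an array. A gene was represented by its probe with the highest mean signal over all 8 arrays. This left 17093 features, 12031 of them with a symbol. The word gene below covers all of them in counts, and only features with a symbol are named.

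The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all features tested, threshold 0.05, no fold threshold). Every adjusted p of a gene below comes from this fit unless another is named, and standard errors (SE) are those of the fitted log2 fold change. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 34 of 35 lists with at least 3 tested members; the mast cell list had fewer. An estimated correlation per list and fry were alternatives. The main design, the lists, the rule for named genes and the alternatives below were written before the data were examined. The rule takes the 10 genes per direction with the largest change among those past the threshold whose arrays do not overlap between groups, up to 4 members with the smallest p of each list that was called or bears on the question, and every member of such a list with at most 10. Results of some genes that the rule takes are not reported here. Other list members are named in places as examples chosen after their values were seen. A gene not well above background on any array of a group is given as "at least" a fold. This sets the bright group's mean against the mean, over the dim arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. The bound holds for the background subtraction of the main values. Normexp with an offset draws dim signals together and gave most of these genes a smaller fold. No spot of the genes named this way was treated as saturated.

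On simulated data drawn from the means and spreads of the 17093 features, with 200 genes changed, the fit for this comparison recovered 53.7% of 67 genes changed by 0.58 on the log2 scale, 80.6% of 67 genes changed by 1 and 97.0% of 66 genes changed by 2, with 10 false calls. It made 0 calls where nothing was changed. Over 20 further draws the mean recovery was 43.4% (32.8% to 55.2%), 74.4% (65.7% to 83.6%) and 93.9% (89.4% to 98.5%), with 3 to 15 false calls. The simulated genes were independent of one another, so the simulation does not test the effect of correlated genes on list tests. It changed 200 genes, whereas 5851 were called in the data. The cutoff that the Benjamini-Hochberg adjustment sets depends on that share. The recovery and the number of false calls therefore do not carry over to the data.

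The alternatives were normexp background correction (offset 50) of the median spot and background intensity, since the deposited scanner tables used here hold no mean signal column; quantile normalization; median centring; no filter on dim probes; a filter requiring all 8 arrays; the mean over a gene's probes; slide row, slide column or neighbouring sample numbers as a block; the authors' value table; array weights; a trended robust prior; a fold threshold of 1.5; an adjusted p under 0.01; and leaving out each array. A planned test of genes with a match to the miR-127-3p seed in their 3' untranslated region was not run, since no transcript sequence was used here. The labels do not say whether the samples came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Sample numbers are not shared between the groups and pair no samples. The number of arrays, 4 per group, limits the precision.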

Results

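To examine what miR-127-3p does to the transcriptome of dermal fibroblasts, messenger RNA was profiled in newborn mouse skin fibroblasts after transfection with control oligonucleotides (n = 4) or with a miR-127-3p mimic (n = 4). The series' title places the work in the context of senescence, a lasting exit from the cell cycle, and of myofibroblasts, the contractile form of the fibroblast. The array measures messenger and long non-coding RNA, so the level of the mature microRNA itself was not analysed here. Between 20756 and 23472 probes per array were well above background. Of 6 quality measures (probes above background, 75th percentile, median, negative controls, local background and the brightest spike-in), none passed a test between the groups (smallest exact permutation p = 0.143, adjusted p = 0.514, two-sided, 70 assignments of 4 and 4 arrays). The smallest exact permutation p that 70 assignments give is 0.0286, so a single measure could not have passed after adjustment over 6. The brightest spike-in differed by -0.22 on the log2 scale (mimic minus control, SD 0.16 in controls and 0.13 with the mimic). Correlations between arrays across genes were 0.984 to 0.992 within the control group, 0.985 to 0.994 within the mimic group and 0.960 to 0.981 between the groups.

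The comparison asked which transcripts differed between mimic and control transfection. Most tested genes of cell division (27 of 28) and DNA replication (29 of 29) fell, while Cdkn1a and most interferon-induced (19 of 26), senescence-associated secretory (14 of 22) and lysosomal genes (14 of 20) rose. No gene list passed its test with an estimated correlation between genes. Of 17093 genes tested, 5851 differed (limma, adjusted p under 0.05), 2717 higher and 3134 lower with the mimic. Of these, 610 were higher and 663 lower by at least 2-fold. Among the 12031 genes with a symbol, 2193 rose and 2422 fell, which is the base rate for the counts within lists. The groups did not overlap in 34.2% of genes, where chance gives 2.86% with 4 against 4. With slide row as a block 5543 genes differed, and within row 1 and row 2 alone (2 arrays per group each) 1759 and 1611 genes did. The median log2 fold change over all genes was 0.02.

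The largest rises were in Hoatz, a gene of ciliated cells, which was not well above background on any control array and was at least 8.79-fold higher with the mimic (adjusted p = 1.19e-05), and in Mmp10, a secreted matrix protease, with a log2 fold change of 4.38 (SE 0.87, adjusted p = 0.00540, n = 4 per group). Mmp10 was well above background on 2 of 4 control arrays. Cend1, a neuronal differentiation gene, was at least 4.31-fold higher, Acp7 at least 4.52-fold and Fibcd1 at least 2.06-fold (adjusted p = 1.28e-05, 0.000595 and 0.000206), with no control array well above background. Log2 fold changes were 3.15 for Stmn4, a microtubule regulator, 3.00 for Eva1c (1 of 4 control arrays above background), 2.92 for Sod3, the extracellular superoxide dismutase, 2.91 for Zbp1, a sensor of nucleic acids, and 2.76 for Tfpi2, a protease inhibitor. Their adjusted p-values lay between 7.13e-05 and 0.00390. The size of these changes depends on how dim signals are treated: with normexp background correction the log2 fold changes were 1.72 for Hoatz, 2.53 for Mmp10, 1.32 for Cend1, 1.16 for Acp7, 0.68 for Fibcd1, 1.22 for Eva1c, 2.47 for Stmn4 and 1.99 for Tfpi2, and all 8 still passed the test.

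The largest falls included Ska1 and Spc24, both parts of the machinery that ties chromosomes to the spindle, with log2 fold changes of -2.91 (SE 0.19) and -2.78 (SE 0.12), and Cdc25c, a phosphatase that opens the way into mitosis, with -2.56 (SE 0.13; 2 of 4 mimic arrays above background). Sgo2a, which protects the cohesion of chromatids, was at least 3.72-fold lower, Dscc1, a clamp-loading factor, at least 3.26-fold and Dna2, a replication nuclease, at least 1.69-fold (adjusted p = 7.79e-05, 0.000888 and 3.34e-05), with no mimic array well above background. The mitotic kinesin Kif15 had a log2 fold change of -2.78 and the repair polymerase Polq of -2.58, with 1 and 2 of 4 mimic arrays above background. Sapcd2 had a log2 fold change of -2.73 and Sprr2k, a gene of the skin's cornified envelope, of -3.35 (1 of 4 mimic arrays above background). With normexp the log2 fold changes were -2.19 for Ska1, -2.03 for Spc24, -1.15 for Cdc25c, -1.23 for Sgo2a, -1.05 for Dscc1, -0.79 for Dna2, -1.10 for Kif15, -1.02 for Polq and -1.51 for Sprr2k, and all 9 still passed the test.

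Whether the mimic changed proliferation was addressed with lists of cell cycle genes. Of 28 tested genes of G2/M and mitosis, 27 fell and 0 rose, and 27 fell when adjusted over the list alone. The mean over arrays of the list's median was -2.00 ± 0.23 (SD, n = 4) with the mimic and 0.01 ± 0.08 in controls. The survivin gene Birc5 had a log2 fold change of -2.20 (SE 0.11, adjusted p = 1.28e-05), the mitotic kinases Plk1 and Bub1 of -2.15 (SE 0.11) and -2.31 (SE 0.12), and the spindle factor Dlgap5 of -1.73 (SE 0.08). The log2 fold change of Dlgap5 ranged from -1.77 to -0.98 over 23 settings. All 29 tested genes of DNA replication and G1/S fell, also when adjusted over the list alone, with a median log2 fold change of -1.18. They include the helicase parts Gins1 (-2.14, SE 0.11), Mcm5 (-1.98, SE 0.12) and Gins2 (-1.13, SE 0.08). Camera gave adjusted p = 3.71e-24 and 4.59e-19 for these lists, and adjusted p = 0.243 for each with an estimated correlation. The G2/M median was -2.00 within slide row 1 and -1.99 within slide row 2.

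**Figure D1:**
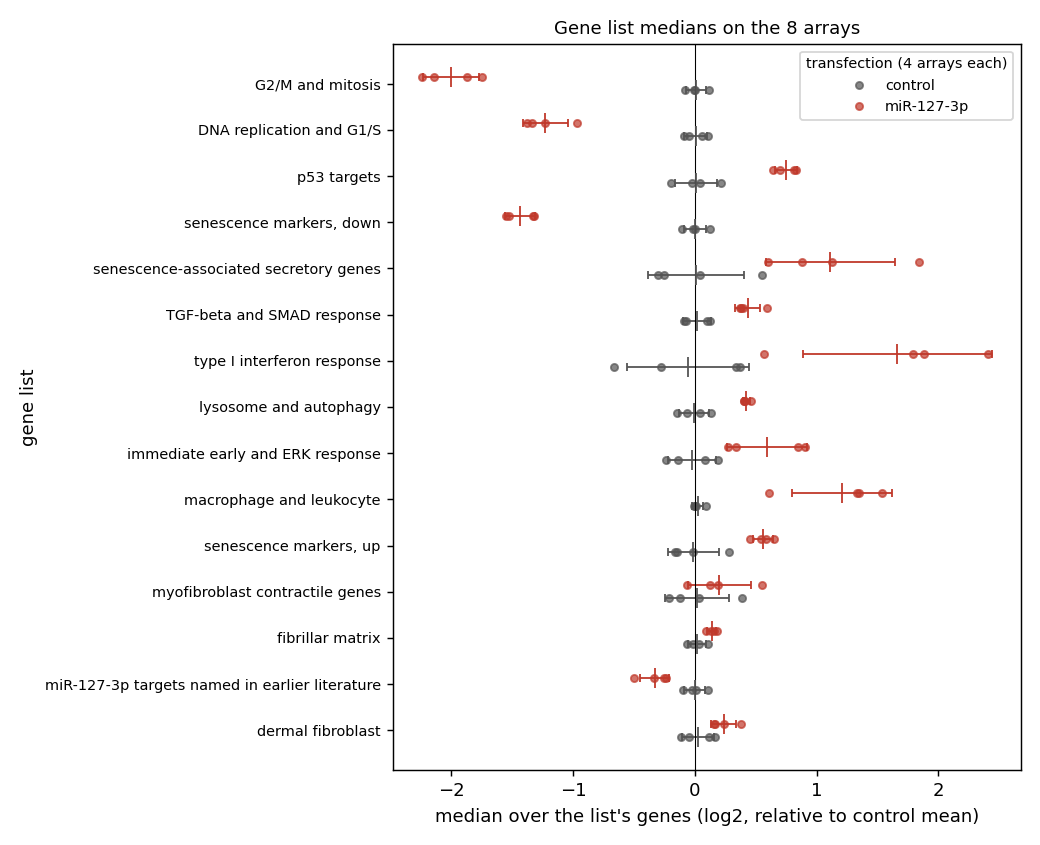
Median over the genes of each list on each array (horizontal axis, log2 relative to each gene's control mean) for control arrays (grey) and miR-127-3p mimic arrays (red); points are arrays, ticks and bars are the mean and SD of 4 arrays. The mimic arrays lie between -2.24 and -1.75 for G2/M and mitosis, below every control array, and between 0.57 and 2.41 for the type I interferon response.

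Genes of the p53 response rose in 15 of 21 tested cases and fell in 0 (17 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 0.74 (camera adjusted p = 1.54e-07; adjusted p = 0.243 with an estimated correlation). The cell cycle inhibitor Cdkn1a had a log2 fold change of 2.38 (SE 0.17, adjusted p = 4.04e-05) and its second probe gave 3.67. The stress protein gene Trp53inp1 (1.64, SE 0.11), Mdm2, which encodes the ligase that degrades p53 (1.14, SE 0.11), and Phlda3 (1.20, SE 0.13) rose as well.

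Markers used for senescence went in several directions. All 5 genes known to fall in senescent cells fell, also when adjusted over the list alone (median log2 fold change -1.38, camera adjusted p = 9.46e-06; adjusted p = 0.243 with an estimated correlation). These were the nuclear lamina gene Lmnb1 (-1.71, SE 0.14), the chromatin proteins Hmgb1 (-1.38, SE 0.10) and Hmgb2 (-2.04, SE 0.12), the histone methyltransferase Ezh2 (-1.36, SE 0.11) and the histone variant H2az1 (-1.14, SE 0.08). Genes of G2/M and mitosis (27 of 28) and of DNA replication (29 of 29) fell in the same comparison. No test set these 5 falls apart from the fall of the cell cycle genes. Of 9 tested markers known to rise, 5 rose and 1 fell (6 and 1 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0841). Beside Cdkn1a, the rises included Igfbp5 (0.91), Plaur (0.86) and Glb1, the gene of the lysosomal galactosidase stained for in senescent cells (0.43). The call of Glb1 was lost with slide column as a block (adjusted p = 0.0670). Cdkn2a fell, with a log2 fold change of -1.46 (SE 0.38, adjusted p = 0.0187). The locus gives rise to separate transcripts for the inhibitors p16 and p19Arf, and its single probe was not assigned to the p16 transcript here, so the value does not measure that senescence marker by itself. Its call was lost without control 1 (adjusted p = 0.0511) or without miR-127-3p 4 (adjusted p = 0.0530), and its log2 fold change ranged from -1.85 to -0.90 over 23 settings. The log2 fold changes of Cdkn2b (-0.55, adjusted p = 0.143), Igfbp7 (0.48, adjusted p = 0.0555) and Igfbp3 (-0.21, adjusted p = 0.840) did not pass the test.

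Of 22 tested genes of the senescence-associated secretory set, which covers cytokines, growth factors and proteases, 14 rose and 0 fell (15 and 0 when adjusted over the list alone). The list's median log2 fold change was 0.86 (camera adjusted p = 1.31e-05; adjusted p = 0.395 with an estimated correlation), and 0.70 with normexp to 1.30 without control 6 over the settings tried. Csf1, a growth factor for macrophages, had a log2 fold change of 0.93 (SE 0.09, adjusted p = 0.000168), the keratinocyte growth factor Fgf7 of 1.23 (SE 0.17), the protease inhibitor Timp1 of 0.73 (SE 0.12) and the plasminogen activator Plat of 0.66 (SE 0.10). Il6 rose by 2.29 (SE 0.50, adjusted p = 0.00840) and Mmp10, named above, belongs to this set. The array medians of the list were 0.60 to 1.84 with the mimic and -0.30 to 0.55 in controls, with control 6 and miR-127-3p 7 the highest of their groups. Other divisions of the 8 arrays into 4 and 4 gave the list a median difference of up to 1.22.

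Myofibroblast genes were examined as contractile genes, fibrillar matrix and the response to TGF-beta, the growth factor that drives the myofibroblast state. Of 19 contractile genes, 2 rose and 0 fell, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.166): Cald1, an actin-binding regulator of contraction (0.63, SE 0.10), and Palld (0.67, SE 0.16). The smooth muscle actin Acta2, the usual myofibroblast marker, had a log2 fold change of -0.04 (SE 0.12, adjusted p = 0.810). Those of Itga11 (-0.45) and Tpm1 (0.56) had adjusted p = 0.0594 and 0.0979. The 5 probes of Tpm1 ranged from -0.23 to 0.56, with 2 of them in the direction given. Of 28 fibrillar matrix genes, 8 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.149). The thrombospondins Thbs2 (1.38, SE 0.20) and Thbs1 (0.81, SE 0.15), the collagen cross-linker Lox (0.91, SE 0.13) and tenascin C, Tnc (0.83, SE 0.14), rose, and the collagen gene Col3a1 fell (-1.07, SE 0.29, adjusted p = 0.0232). Of 19 genes of the TGF-beta and SMAD response, 10 rose and 3 fell (11 and 3 when adjusted over the list alone; median 0.55, camera adjusted p = 0.00882; adjusted p = 0.243 with an estimated correlation). Ltbp2, a matrix protein related to those that store TGF-beta (1.68, SE 0.11), the ligand gene Tgfb1 (0.89, SE 0.10) and the feedback inhibitor Pmepa1 (1.14, SE 0.16) rose, while Tgfbi, named for its induction by TGF-beta, fell (-2.06, SE 0.34, adjusted p = 0.00244). Within slide row 1 alone this list was not called (median 0.44, adjusted p = 0.05004).

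**Figure D2:**
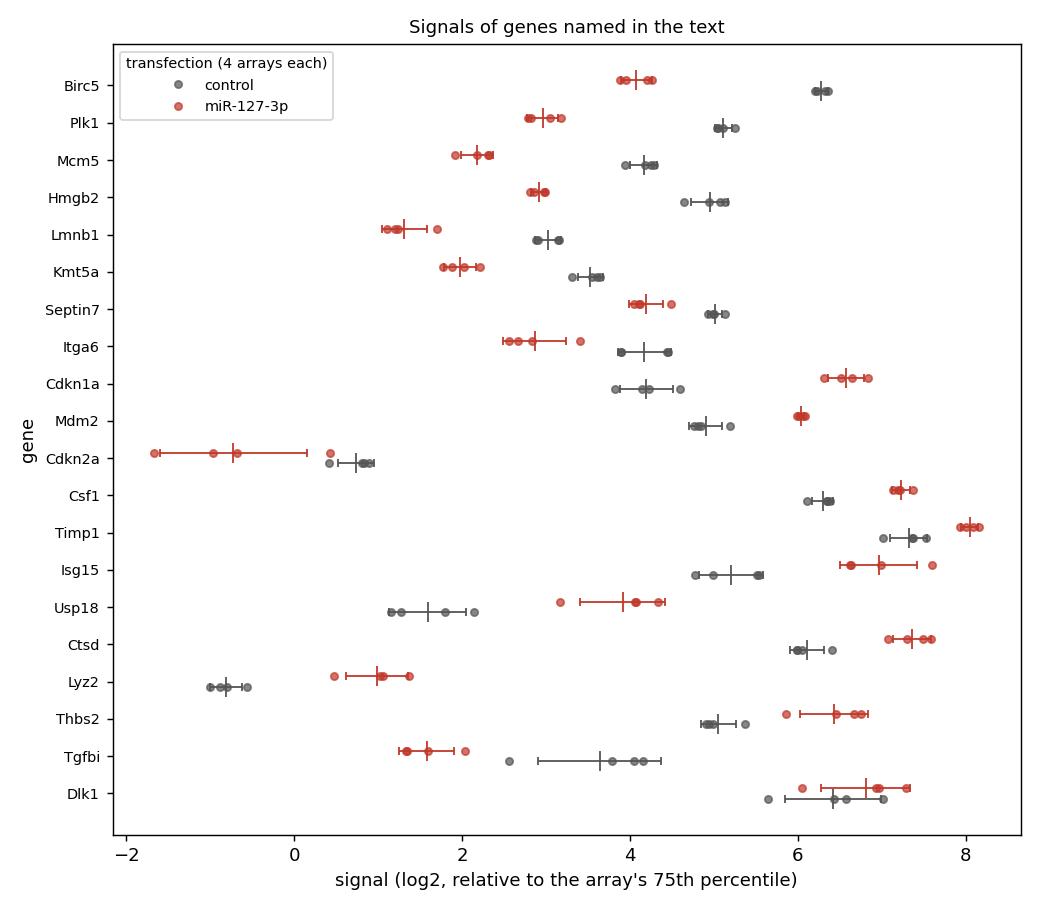
Signal of named genes on each array (horizontal axis, log2 relative to the array's 75th percentile) for control arrays (grey) and miR-127-3p mimic arrays (red); points are arrays, ticks and bars are the mean and SD of 4 arrays. Levels can be compared between groups for a gene but not between genes. Cdkn1a went from 4.20 ± 0.32 to 6.57 ± 0.22 and Birc5 from 6.28 ± 0.07 to 4.08 ± 0.19 (SD, n = 4), while the groups overlap for Cdkn2a and Dlk1.

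Because a transfected RNA duplex can be sensed by the cell, interferon-induced genes were listed beforehand. Of 26 tested, 19 rose and 0 fell (21 and 0 when adjusted over the list alone), with a median log2 fold change of 1.69 (camera adjusted p = 3.17e-07; adjusted p = 0.489 with an estimated correlation). Usp18, which dampens interferon signalling, had a log2 fold change of 2.32 (SE 0.29, adjusted p = 0.000617), Xaf1 of 1.96 (SE 0.28), the ubiquitin-like Isg15 of 1.76 (SE 0.26) and Ifi35 of 1.09 (SE 0.18). The array median of the list was 1.66 ± 0.78 (SD, n = 4) with the mimic and -0.06 ± 0.50 in controls. It was lowest among mimic arrays in miR-127-3p 5 (0.57), and the highest control was control 6 (0.37). Within slide row 1 alone 15 of the 26 rose, and within row 2 alone 0 did, with medians of 1.87 and 1.26 (camera adjusted p = 2.53e-13 and 0.000839).

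Of 18 genes of the immediate early and ERK response, 6 rose and 0 fell, also when adjusted over the list alone (median 0.59, camera adjusted p = 0.00544; adjusted p = 0.395 with an estimated correlation). They include the phosphatases Dusp1 (1.31, SE 0.20), Dusp4 (1.21, SE 0.21) and Dusp6 (0.48, SE 0.09), which switch off MAP kinases, and the AP-1 subunit gene Fosl1 (0.82, SE 0.13). Of 20 lysosome and autophagy genes, 14 rose and 0 fell (15 and 0 when adjusted over the list alone; median 0.45, camera adjusted p = 2.82e-05; adjusted p = 0.345 with an estimated correlation). The lysosomal protease Ctsd (1.25, SE 0.14), the autophagy enzyme Atg7 (1.15, SE 0.11) and the membrane protein Lamp1 (0.53, SE 0.09) were among the members that rose.

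Whether genes reported earlier as targets of miR-127-3p were lower was examined with a list taken from general knowledge. Of 8 tested, 4 fell and 0 rose (4 and 2 when adjusted over the list alone). Of all 12031 tested genes with a symbol, 2422 fell and 2193 rose. Whether the 4 falls came from a sequence match to the microRNA was not tested. The list's median was -0.33, and the list was not called by camera (adjusted p = 0.166) but was by fry (adjusted p = 0.000411, which tests whether the genes move on balance one way). The histone methyltransferase Kmt5a had a log2 fold change of -1.55 (SE 0.12, adjusted p = 5.02e-05) with its second probe at -0.72, the cytoskeletal gene Septin7 of -0.82 (SE 0.11, adjusted p = 0.000834) and the laminin receptor subunit Itga6 of -1.31 (SE 0.22, adjusted p = 0.00234). Kif3b had one of -0.46 (SE 0.15, adjusted p = 0.0406), and its call was lost in 12 of 23 settings, among them the removal of any of 5 arrays (control 6, or miR-127-3p 2, 4, 5 or 7), slide row or column as a block, and normexp, which gave -0.20 (adjusted p = 0.118). Bcl6 (0.52, adjusted p = 0.0618), Mmp13 (2.37, adjusted p = 0.0713), Xbp1 (-0.19, adjusted p = 0.187) and Prdm1 (0.25, adjusted p = 0.627) did not pass. Rtl1, which lies opposite the miR-127 gene, was below the filter on background.

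The microRNA's own region, the Dlk1-Dio3 imprinted domain, was represented by 4 tested genes. Of these, 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.292). The long non-coding RNA Meg3 had a log2 fold change of 0.53 (SE 0.13, adjusted p = 0.0138), its probes ranging from 0.26 to 0.53. Only the strongest of its 3 probes passed the test. Mirg (0.25, adjusted p = 0.0905), Dlk1 (0.39, adjusted p = 0.394) and Begain (-0.13, adjusted p = 0.818) did not pass, and Rian, Dio3, Dio3os and Rtl1 were not tested for lack of signal.

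Markers of other skin cell types were measured beside these groups. Of 9 tested macrophage and leukocyte markers, 8 rose and 0 fell (9 and 0 when adjusted over the list alone), with a median log2 fold change of 1.18 (camera adjusted p = 0.000196; adjusted p = 0.393 with an estimated correlation). They were the lysozyme gene Lyz2 (1.79, SE 0.18), the complement genes C1qa (1.37, SE 0.28) and C1qb (0.90, SE 0.20), Cd68 (1.30, SE 0.25), the receptor gene Csf1r (1.04, SE 0.14), Tyrobp (1.21, SE 0.26), Fcer1g (1.09, SE 0.32) and Itgam (0.51, SE 0.16). The 3 probes of Csf1r ranged from 0.14 to 1.32, and 2 of them passed the test. The calls of Fcer1g and Itgam were lost in 9 and 11 of 23 settings, among them the removal of any 1 of 6 arrays (adjusted p up to 0.0791 and 0.0933), and Adgre1 did not pass (1.18, adjusted p = 0.0981). The secretory, interferon and lysosomal lists rose in the same comparison as these markers. Within slide rows 1 and 2 alone the median was 1.47 and 0.83. Of 10 dermal fibroblast markers, 3 rose and 1 fell, also when adjusted over the list alone (median 0.24, camera adjusted p = 0.327): Col1a1 was at 0.07 (SE 0.11), Thy1 at 0.02 (SE 0.09) and Pdgfra, which fell, at -0.97 (SE 0.21). Skeletal muscle and adipocyte markers (medians -0.19 and -0.03) had no member that passed, and their array medians were lowest in control 3 (-1.34 and -0.83) and miR-127-3p 5 (-1.91 and -1.19).

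The remaining lists were not called by camera. In the unfolded protein and integrated stress response, 10 of 20 genes fell and 2 rose (11 and 2 when adjusted over the list alone; camera adjusted p = 0.0669), with falls in Edem1 (-1.39, SE 0.18), a factor of protein quality control, and the pseudokinase gene Trib3 (-1.32, SE 0.17). Of 13 genes of the microRNA pathway, 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.264), among them Dicer1, which cuts microRNA precursors (-1.28, SE 0.16, adjusted p = 0.000591). Of 25 oxidative phosphorylation genes 5 fell and 1 rose (2 and 0 when adjusted over the list alone), and of 15 YAP target genes 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0646 and 0.0954). Of 21 cholesterol synthesis genes 3 fell and 0 rose (1 and 0 when adjusted over the list alone; camera adjusted p = 0.107), of 13 Wnt genes 3 rose and 1 fell, of 13 imprinted growth genes 3 rose and 2 fell, of 19 NRF2 targets 1 rose and 2 fell, of 19 glycolysis and hypoxia genes 1 rose and 1 fell, and of 25 ribosomal protein genes 0 rose and 2 fell. Keratinocyte, melanocyte, endothelial and Schwann cell markers each had 1 member that rose and 0 that fell (of 6, 6, 4 and 3), and pericyte markers 1 that fell of 3. None of 12 NF-kB feedback genes passed the limma test, and control 6 and miR-127-3p 7 had the highest medians of that list (1.41 and 1.48).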

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

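All explanations weighed in this part were raised after the patterns had been seen, and the tests on fibroblast markers and on the other cell types together were also chosen after their result was seen, as was the correlation used for a criterion on interferon genes that had been written before. The values flagged here are arrays whose gap to the nearest array of their group, divided by the group's range, exceeded the 5% critical value of Dixon's ratio for 4 values. Chance flags about 1 in 20 groups, or 13.1 of the 262 groups of 4 arrays looked at, and 21 were flagged. The groups cover the array quality measures, the list medians and the named genes reported here.

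Several flagged values belonged to the arrays control 3 and miR-127-3p 5. Control 3 was the highest control for Eva1c (0.883 of the range), Plaur (0.939), Tnc (0.858), Ctsd (0.861) and the median of the YAP targets (0.947), and the lowest for Spc24 (0.899). MiR-127-3p 5 was the highest mimic array for Cdkn2b (0.883), Thbs1 (0.879) and Septin7 (0.831) and the lowest for Hoatz (0.876). Control 6 was the highest control for the median of the NF-kB feedback genes (0.891). Control 8 was the lowest control for the medians of the NRF2 targets (0.880) and Schwann cell markers (0.841) and the highest for Dna2 (0.942). Control 1 was the lowest for Csf1 (0.854) and the highest for the macrophage and leukocyte median (0.833). MiR-127-3p 4 was the highest mimic array for the TGF-beta and SMAD median (0.901) and Phlda3 (0.835). MiR-127-3p 7 was the lowest for the cholesterol synthesis median (0.927) and the highest for Dlgap5 (0.870), and miR-127-3p 2 the highest for the lysosome and autophagy median (0.838).

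Chance division of the arrays is argued against for the number of genes that differed, but not for the number of gene lists that camera called. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many as 5851 genes, and the highest of the others called 5. A share of 1 in 35 is the smallest that these splits can give. Every other split also leaves the mimic difference in the spread within its groups, which lowers its count of genes. For the lists, 21 of the 35 splits called at least 10, and another split called 17. This count cannot show how often chance alone calls lists, because splits that mix the groups unevenly keep part of the mimic difference. Such splits, the real one aside, called 9 to 17 lists, with 17 where control 1 stood with miR-127-3p 2, 4 and 7. Splits that mix the groups evenly, which balances that difference, called 0 to 14 lists. Some of these evenly mixed splits therefore reached the real count of 10. Single lists fared differently: for 9 of the 10 called lists the median log2 fold change was larger in size under the real split than under any other (2.00 against at most 1.18 for G2/M and mitosis, 1.69 against 1.63 for the interferon list), the exception being the secretory list with 0.86 against 1.22. The median was also largest under the real split for 4 lists that were not called (senescence markers known to rise, unfolded protein response, dermal fibroblast and keratinocyte markers), so it does not set the called lists apart.

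The fall of the G2/M and mitosis genes was weighed against scaling between arrays and against a changed cell mixture. Under the 75th percentile, median and quantile scalings the list's median stayed at or below -1.98, which argues against the choice among these 3 as the cause. Each of them aligns the arrays on their probes as a whole. A shift in RNA amount shared by most genes would therefore not be seen under any of them. Fewer fibroblasts among cells that do not divide would lower the fibroblast markers by about as much, but their median was 0.24, with an SD of at most 0.13 between arrays. Lower proliferation after the mimic remains a hypothesis that fits these values. No count of cells was analysed here.

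The rise of the macrophage and leukocyte markers may reflect more leukocytes among the mimic-transfected cells. A set of 28 further leukocyte genes was written after the rise of the markers but before their own values were seen: the 16 that passed the filter on background had a median log2 fold change of 1.22, and 13 rose and 0 fell, including the abundant macrophage transcripts Ctss (1.55), Pf4 (1.76) and C1qc (1.51). Some of the 16 passed the filter mainly through the mimic arrays, so the filter in part favours a rise. Fcgr3 was above background on 0 control and 4 mimic arrays, and Cd52, Mrc1 and Rac2 on 1 and 3. A lower share of fibroblasts, which would raise every other cell type alike, is argued against only by a mean over 7 other cell types. The leukocyte median rose by 0.85 more than that mean (exact permutation p = 0.0286, the smallest that 70 assignments give). In a first version with 3 types it rose by 1.12 more. Among the 7, the melanocyte (0.93), Schwann cell (0.67) and keratinocyte (0.53) medians rose too. Those of endothelial (0.14), pericyte (0.08), adipocyte (-0.03) and skeletal muscle (-0.19) markers were lower. The adipocyte and muscle medians varied widely between arrays. Induction of the leukocyte genes inside fibroblasts cannot be told apart from a larger share of leukocytes. Of the 28 further genes, 13 were above background on all 4 mimic arrays, 1 short of the 14 set beforehand for arguing against induction. Spi1, Cd53 and Cybb were above background on none. Over the arrays within the groups, the leukocyte median followed that of the interferon list (correlation 0.755, n = 8; mimic arrays 2, 4, 5 and 7: 1.35, 1.54, 0.61 and 1.33 against 1.88, 1.79, 0.57 and 2.41), which had been written down as a sign of induction, so both explanations stay open.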

How the results depend on the processing

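Choices added after seeing the data were the removal of control 6 with miR-127-3p 7, the removal of control 3 with miR-127-3p 5, and each slide row alone. The number of genes that differed (5851; 2717 higher, 3134 lower) stayed within 1.5 times under 10 planned settings of scaling, filter, probe choice, values, weights, prior and block, except as follows. Without a filter on dim probes, 3592 genes differed (1695 higher, 1897 lower) among 21361 tested, and the median over all genes was 0.12. With slide column as a block, which leaves fewer degrees of freedom, 1780 were higher. With a fold of at least 1.5 as well, 2960 differed (1438 and 1522), and at an adjusted p under 0.01, 3262 (1376 and 1886), both stricter by construction. Without control 6 and miR-127-3p 7, 3613 differed (1643 and 1970). With 2 arrays per group, row 1 alone gave 1759 (768 and 991) and row 2 alone 1611 (685 and 926). Leaving out each array gave 4320 to 5789 genes (1864 to 2899 higher, 2456 to 3073 lower) and 10 to 13 gene lists. Of 10 gene lists called, 0 were called with an estimated correlation, which was 0.62 for G2/M and mitosis, and fry, which does not compare a list with other genes, called 19. The 10 calls held under every other planned setting run for the lists, and some settings added calls: 14 lists were called without a filter, 12 with normexp, and 11 with quantile normalization or slide column as a block. Lists not called passed in some of them, with a smallest camera adjusted p = 0.00527 for the unfolded protein response and for oxidative phosphorylation, 0.0425 for the senescence markers known to rise, 0.0330 for contractile genes, 0.0265 for YAP targets, 0.0117 for cholesterol synthesis and 0.0432 for NF-kB feedback genes. Of 81 named genes called, 27 lost the call in row 2 alone, 20 in row 1 alone, 8 without control 6 and miR-127-3p 7, 8 at an adjusted p under 0.01, 6 with the fold threshold, and 0 to 4 under any other setting. No named gene or list that was called reversed its direction, while 2 of all genes called did so, called in the opposite direction with the mean over a gene's probes. Among those not called, signs changed for Igfbp3 (-0.86 to 0.37), Prdm1 (-0.06 to 0.48), Begain (-0.41 to 0.09) and the medians of skeletal muscle (-0.69 to 0.20), adipocyte (-0.35 to 0.48) and Schwann cell markers (-0.31 to 0.87), among others. The seed-match test and its alternatives were not run. Genes not above background on any array of a group have a bound on their fold. Those above it on only some arrays have a log2 fold change that rests in part on dim signals. Normexp with its offset, which compresses dim signals by construction, shrank both.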

Other observations

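The families below were defined by symbol after the data were examined, and the tests of this part were chosen after the result was seen, except the count of splits with the first family definitions. Of 22 gene families tested, camera called 14, and 0 with an estimated correlation (smallest adjusted p = 0.0640). Centromere proteins fell in 17 of 20 cases, nucleoporins in 13 of 18, Fanconi anaemia genes, which repair DNA cross-links, in 8 of 9, and SR splicing factors in 7 of 10, with 0 rising in each. Fanca had a log2 fold change of -2.01 (SE 0.14, adjusted p = 2.80e-05) and Fancd2 was at least 2.00-fold lower (adjusted p = 0.00140). Clustered histone genes went both ways: 25 of 32 fell and 5 rose, with H2bc4 at 1.53 (SE 0.23). Probes of these histone genes were not checked for shared sequence, so the counts may include the same transcript more than once. Among kinesins, 15 of 29 fell, while 4 rose: Kif5a (1.71, SE 0.13), Kif1a (1.58, SE 0.19), Kif5c (0.98, SE 0.20) and Kif21a (0.50, SE 0.17).

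Cathepsins rose in 9 of 11 cases, subunits of the vacuolar ATPase, the pump that acidifies lysosomes, in 10 of 17, and laminins in 7 of 11, with 0 falling in each. The leukocyte markers rose in the same comparison, and Ctss, 1 of these 9 cathepsins, is itself a leukocyte gene (1.55). Lama2 had a log2 fold change of 1.39 (SE 0.11, adjusted p = 6.38e-05), and Lamc3 was at least 5.26-fold higher (adjusted p = 3.27e-05). Among integrins 8 of 18 rose and 1 fell. Itgam, 1 of these 8, is also on the list of leukocyte markers (0.51). With the first definitions of the families, 4 of the 35 splits of the arrays called at least 14, the highest other 14. With 4 definitions corrected for stray members, 1 split, the real one, did, the highest other 13. The families were defined after these data were examined, and the 4 corrections were made after the first count was seen. Neither count can therefore argue against chance. As with the lists above, some of the other splits keep part of the difference between the groups.

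Deviations from the group means correlated across genes, which are not independent, for control 6 with miR-127-3p 7 (0.56), control 8 with miR-127-3p 2 (0.52) and control 3 with miR-127-3p 5 (0.50). The highest value of both remaining arrays, control 1 and miR-127-3p 4, was with each other (0.18). The labels give no such pairing, and no fit used it.

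Some genes set the mimic arrays of slide row 1 (miR-127-3p 2 and 4) apart from those of row 2 (miR-127-3p 5 and 7). Hmox1, the haem oxygenase gene, was at 1.29 and 1.72 in row 1, at 5.01 and 5.51 in row 2, and at 4.86 to 5.20 in controls, and a second probe differed between the rows by -2.46. The interaction of group and row had an adjusted p = 0.118 for Hmox1 (limma, n = 8), and 0 genes passed, with 883 at an unadjusted p under 0.05. By size alone (over 1 between the rows and under 0.6 within each), 71 genes split the mimic arrays this way, but 64 genes split them as 2 and 5 against 4 and 7, so chance cannot be told apart from a real division. Only 27 of the 71 had a symbol, against 40 of the 64, and features without a symbol were not checked for shared sequence, so the 71 may count the same transcript more than once. With a limit of 0.8 on the range over the controls as well, the numbers were 56 and 23. The 71 genes did not share 1 pattern against controls. Like Hmox1, Lamtor2 was lower in mimic row 1 alone (-1.40 in row 1, 0.08 in row 2). Gm5176 was below controls in both rows, by different amounts (-2.72 and -1.26). In the 71 genes the control arrays of the 2 rows differed by 0.11 at the median against 1.26 in the mimic arrays, which argues against slide position. Other probes existed for few of the 71 genes, and 6 of 8 such probes showed the difference. Among genes with a symbol, those of Hmox1 and Cped1 did, and those of Zfp955b and Prelid3a did not. Bad probes are therefore argued against only for the genes whose other probe agreed. Slide row goes with sample number, and no biological explanation was tested.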
